A study of Mus musculus and Homo sapiens with 20 samples.

How the data were processed

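RNA sequencing of total RNA was used to profile 20 libraries, 11 from mouse prostate and 9 from 22Rv1, an established human prostate carcinoma line. Each mouse library came from the right anterior lobe of the prostate. The WT group had 6 libraries without Cre recombinase, 4 of them from animals with both Chd1 alleles flanked by loxP sites and 2 from animals with ordinary alleles. The Chd1_del group had 5 libraries from animals with the floxed alleles and Cre under the probasin promoter, which is active in prostate epithelium. The human libraries formed 3 groups of 3, in which CHD1 was intact (wildtype), deleted on one allele (het_del) or deleted on both (hom_del). Groups were taken from the sample labels. The 3 libraries of each edited group share a name prefix in the labels, as replicates of a single clone would, so an effect of genotype cannot be separated from a difference between clones. The labels do not say whether replicates came from separate cultures, so their p-values measure the spread between these samples, which may be technical.

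Per the labels' protocols, libraries were made and sequenced at a UCLA core facility and at an ICR profiling unit, and RNA of the 22Rv1 cells was extracted with a column kit. The submitters' processing notes name TopHat2 (versions 2.0.13 and 2.0.7), Bowtie, Cufflinks 2.2.1 and Cuffdiff, with the builds mm9 for mouse and hg19 and GRCh37 for human. Which version served which species, the gene annotation and the use of strand are not given in the sources used here.

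The authors deposited one table per species with a value in FPKM (fragments scaled to transcript length and to the mapped fragments of the library) for each gene and library. The mouse columns carry that unit per the file headers. The human columns carry no unit, and FPKM was inferred from the quantification tools in the submitters' processing notes and from the range of the values. The mouse table also gives the authors' mean FPKM of each group and their own p-value and q-value per gene, per the file headers, and these were used only as the authors' deposited comparison. The mouse file has 23907 entries, of which 27 carry a calendar date in place of a gene symbol and were left out. Of these entries 10278 hold a 0 in at least 1 library and 6120 hold a 0 in every library. Some zeros may be failed estimates, which was not tested: Hmgcs1 is listed at 0 in all 11 libraries, Gapdh at 0 in 4 and at no more than 0.536 in the others. Probasin (Pbsn) has 0 as the authors' WT mean although its 6 WT libraries hold 3378 to 5902 FPKM. The human file has 14096 entries and no value of exactly 0, though 59 of the 12531 tested genes have a value under 0.001 FPKM in at least 1 library, among them ZNF512 in het_del. 10 human symbols stand on 21 entries, which were kept apart.

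FPKM values carry no read counts, so the depth of each library is unknown and no counting interval is given. The sum of FPKM ranged from 376988 to 543371 in mouse and from 1796257 to 6292547 in human libraries. RNU4-2, a spliceosomal RNA, made up 25.0 to 29.1% of the sums in wildtype and 30.1 to 38.4% in the edited libraries, without overlap. Genes that share sequence with close copies, such as small nucleolar RNAs, histones and class I HLA genes, and genes that overlap another gene carry values that the authors' counting may have split.

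Values were taken as log2(FPKM + 1), so that changes of genes with low values are understated. Genes with a mean of at least 1 FPKM over the libraries of a species were tested, 11866 in mouse and 12531 in human. Differences were tested with limma (version 3.58.1 in R 4.3.3, with data.table at version 1.17.8), using lmFit and eBayes with a mean-variance trend, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The 3 human groups shared 1 fit. Every log2 fold change below is on that scale, and every adjusted p of a gene comes from these fits. Chd1 and CHD1 were also compared with exact permutation tests, two-sided.

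28 gene lists were tested with camera from limma, with a preset correlation of 0.01 between genes and Benjamini-Hochberg adjustment over the lists with at least 5 tested members. They covered the CHD family, chromosomal neighbours of CHD1, homologous recombination, end joining with the resection barrier, alternative end joining, damage signalling, p53 targets, androgen-responsive genes, proliferation, interferon response, NF-kB targets, the unfolded protein and amino acid stress response, glycolysis and hypoxia, sterol synthesis, mesenchymal transition, ribosome biogenesis and immediate early genes. The remaining lists hold markers of luminal, basal and neuroendocrine or neuronal cells, smooth muscle, fibroblasts, endothelium, immune cells, seminal vesicle, urothelium, adipocytes and skeletal muscle. Camera with an estimated correlation and fry were run as alternatives. The PValue of fry tests whether the genes of a list move on balance in one direction, without comparing them with other genes.

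The groups, the tests, the lists, the rule for named genes and most alternatives were set before the data were examined. The rule takes the targeted gene, then the 10 largest rises and 10 largest falls per comparison among genes with an adjusted p under 0.05 whose groups do not overlap, leaving out provisional symbols, then up to 4 members per list with the smallest adjusted p. Where no gene passed, the 5 with the smallest p in each direction are given as not passing. The alternatives were a pseudocount of 0.1 FPKM, no filter and a minimum mean of 5 FPKM, upper-quartile and quantile scaling, robust variances, library quality weights, leaving out each library, floxed WT animals alone, the series of animal identifiers or the human replicate numbers as a block, and the 2 groups of a human comparison alone. Fits without libraries that stood apart were added after the values were seen. Tests on counts were not run because the values are not counts.

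The fits were tested on simulated data in which 200 genes were changed by a known amount. In the mouse design of 11866 genes, 51% of genes changed by 0.5 on the log2 scale were recovered, 88% at 1 and 99% at 2, with 4, 5 and 11 false calls. For hom_del against wildtype with 12531 genes, 0% were recovered at 0.5, 12% at 1 and 84.5% at 2. For het_del against wildtype the shares were 0%, 12.5% and 85.5%, and for hom_del against het_del 0.5%, 18% and 87.5%. Camera found a list of 20 genes shifted by 1 in 100% of 100 simulations of hom_del against wildtype and called 0.2% of unshifted lists. The simulated genes varied independently and the lists were random. These shares therefore do not carry over to lists whose genes vary together, such as proliferation in human (estimated correlation 0.841). Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.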

Results

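The data are total RNA profiles of 20 libraries in which the chromatin remodeller CHD1 was deleted or left intact. In mouse, 6 WT and 5 Chd1_del libraries came from the right anterior prostate, and in 22Rv1 cells 3 wildtype, 3 het_del and 3 hom_del libraries were compared. The study asks how loss of CHD1 bears on prostate cancer and on the repair of DNA double-strand breaks. The depth of the libraries is unknown because values are FPKM. Spearman's rho between libraries across genes, which are not independent replicates, was 0.931 to 0.979 in mouse and 0.851 to 0.959 in human, and no 2 libraries were identical.

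The targeted gene was compared first. In the mouse prostate Chd1 was at 5.68 ± 0.917 FPKM (mean ± SD, n = 6) in WT and 5.08 ± 0.582 (n = 5) in Chd1_del. The log2 fold change was −0.13 (SE 0.105), with an adjusted p of 0.971 and an exact permutation p of 0.238 over 462 splits, where 0.00433 is the smallest possible. FPKM of the whole gene does not measure the floxed exons, and Cre under the probasin promoter acts in epithelium alone, so these values do not check the deletion. In 22Rv1 cells CHD1 (ENSG00000153922, chromosome 5, 98190907 to 98262240 as the file gives it) was at 20.5 ± 1.83 FPKM (n = 3) in wildtype, 9.18 ± 2.86 (n = 3) in het_del and 8.46 ± 1.36 (n = 3) in hom_del. CHD1 fell by 1.11 (SE 0.235) on the log2 scale in het_del (adjusted p = 0.0187) and fell by 1.19 (SE 0.235) in hom_del (adjusted p = 0.0266). All 6 edited libraries, at 6.51 to 12.2 FPKM, were below all 3 wildtype libraries, at 19.0 to 22.5 FPKM. CHD1 did not differ detectably between hom_del and het_del (log2 fold change −0.08, adjusted p = 0.913). The exact permutation p was 0.1 for each edited group against wildtype, the smallest that 20 splits allow, and 0.9 between the edited groups. The level of the transcript in hom_del does not show how much intact protein was left. In hom_del against wildtype the adjusted p of CHD1 rose past 0.05 without any single library: 0.0796, 0.0707 and 0.0647 without wildtype 1, 2 and 3, and 0.0536, 0.0882 and 0.0573 without hom_del 1, 2 and 3. In het_del against wildtype it was 0.0588 and 0.0518 without wildtype 1 and 2, and 0.0686 and 0.0852 without het_del 2 and 3.

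**Figure D1:**
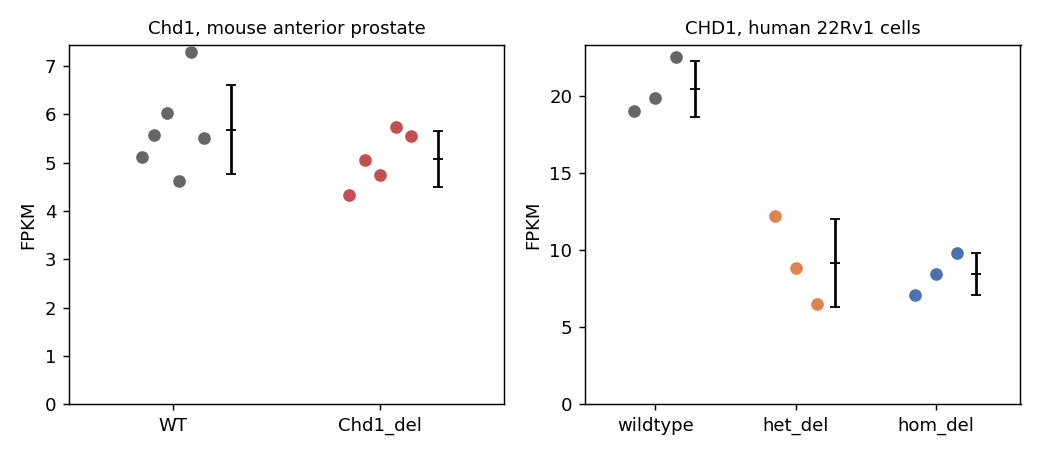
FPKM of Chd1 in mouse prostate (left) and CHD1 in 22Rv1 cells (right), one point per library, with bars for the mean and SD of each group. WT and Chd1_del overlap around means of 5.68 and 5.08, whereas het_del (9.18) and hom_del (8.46) lie below wildtype (20.5).

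No single gene passed the threshold between the mouse groups. Fam195b was at 61.6 ± 8.63 FPKM (n = 6) in WT and 36.3 ± 3.55 (n = 5) in Chd1_del, the difference with the smallest p. Myef2, a transcriptional repressor of myelin genes, was at 5.40 ± 0.417 FPKM (n = 6) and 3.98 ± 0.348 (n = 5). Prss28, a serine protease, was at 1.01 ± 0.352 FPKM (n = 6) in WT and 2.34 ± 0.522 (n = 5) in Chd1_del. With limma no gene of 11866 passed the threshold: 0 had an adjusted p under 0.05, and 440 had an unadjusted p under 0.05, 250 higher and 190 lower in Chd1_del. Groups did not overlap for 44 genes (0.371%), against 0.433% by chance. The log2 fold change of Fam195b was −0.74 (SE 0.10, adjusted p = 0.0971). It passed without WT 5 (adjusted p = 0.0166), with upper-quartile scaling (0.0299), with quantile scaling (0.00851) and with library quality weights (0.0103). These were 1 of 11 fits without 1 library and 3 of 10 other settings. Fam195b did not pass against floxed WT animals alone, with the series of animal identifiers as a block or with robust variances. Farsb (−0.48), Plscr2 (−0.41) and Tdrd7 (−0.27) were the next lowest in p among lower genes, and Sat2 (0.70), Mccc2 (0.24), Slc25a11 (0.20) and Gstt1 (0.49) among higher genes, all with an adjusted p of 0.971.

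No gene or list of DNA repair passed the threshold in mouse. Rbbp8, which starts resection of broken ends, was at 3.60 ± 1.12 FPKM (n = 6) in WT and 2.84 ± 0.159 (n = 5) in Chd1_del. Parp1, a sensor of strand breaks, was at 15.8 ± 3.05 and 14.2 ± 0.938 FPKM, and the checkpoint kinase gene Chek2 at 2.22 ± 1.01 and 3.00 ± 0.395 FPKM. The remodeller gene Chd1l was at 3.09 ± 0.327 and 4.07 ± 0.484 FPKM. None of the 4 passed (adjusted p = 0.971 for each). The median log2 fold change was −0.01 in homologous recombination (10 genes tested, camera adjusted p = 0.81), −0.05 in end joining (13, 0.81), −0.06 in alternative end joining (7, 0.349), 0.00 in damage signalling (16, 0.992) and 0.01 in the CHD family (9, 0.81). For damage signalling the mean was 0.02 while camera ranked the list as lower. Of the chromosomal neighbours of Chd1 only Riok2 (0.12) and Rgmb (0.04) were tested, too few for camera.

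With camera at its preset correlation, and neither with an estimated correlation nor with fry, immediate early genes ranked lower and sterol synthesis genes higher in Chd1_del. Of the immediate early genes, which respond to stimuli within minutes, Jun was at 70.4 ± 24.7 FPKM (n = 6) in WT and 42.8 ± 7.81 (n = 5) in Chd1_del, and Atf3 at 40.4 ± 9.55 and 29.6 ± 4.02. All 14 tested members had a negative log2 fold change, with a median of −0.18 (camera adjusted p = 0.000208, and adjusted p = 0.944 with an estimated correlation). Part of this difference stood in single WT libraries: against the WT mean the list median was 0.36 in WT 5, 0.06 in WT 6 and 0.04 in WT 4, but −0.31 to −0.13 in WT 1 to 3, where Chd1_del libraries had −0.30 to −0.10. The heat shock genes Hspa1a and Hspa1b, chosen after their values were seen, did not pass (adjusted p = 0.971 for each) and were highest in WT 4 (96.3 and 212 FPKM), followed by WT 1. In the other 9 libraries they were at no more than 13.9 and 42.6 FPKM. Sterol synthesis genes were higher in 16 of 17 members, with a median of 0.16 (camera adjusted p = 0.00612, and adjusted p = 0.944 with an estimated correlation). Fdft1 was at 10.9 ± 2.79 FPKM (n = 6) in WT and 14.2 ± 2.97 (n = 5) in Chd1_del, and Insig1 at 17.6 ± 3.4 and 22.0 ± 5.22. With fry the smallest adjusted p of any of the 24 lists was 0.882. Against floxed WT animals alone both lists had an adjusted p of 0.056, and with the series of animal identifiers as a block 0.0753 (immediate early genes) and 0.577 (sterol synthesis). In the first series of animals alone the immediate early list had 0.771 and the sterol list 0.00158. The sterol list also missed the threshold without WT 1 (0.0783), WT 5 (0.128) or Chd1_del 4 (0.674).

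Transcripts of other tissues were the largest differences in the mouse libraries, and they stood in single libraries. The seminal vesicle gene Svs2 was at 65980 FPKM in Chd1_del 1, 19370 in Chd1_del 3 and 1743 in WT 6, and at 8.07 to 37.6 in the other 8 libraries. Svs5 was at 35260 FPKM in Chd1_del 1 and 14270 in Chd1_del 3, and Pate4 at 16650 and 6166. The median log2 fold change of the 5 seminal vesicle genes was 2.89 (camera adjusted p = 0.0512). Of adipocyte genes, Fabp4 was at 97.7 FPKM in Chd1_del 1 and 84.9 in Chd1_del 2 against at most 24.4 in WT, and Cfd at 66.5 and 84.5 against at most 12.7. Adiponectin (Adipoq), listed at 0 in WT 4 and Chd1_del 4, was at 31.3 FPKM in Chd1_del 1 and 26.9 in Chd1_del 2. The 6 adipocyte genes were higher, with a median of 1.45 (camera adjusted p = 0.000208, adjusted p = 0.944 with an estimated correlation, and 0.988 without Chd1_del 1, 2 and 3). Urothelium had 4 tested genes, of which Upk2 (1.84 ± 0.552 FPKM, n = 6, and 2.80 ± 0.298, n = 5) was the 1 past the threshold when adjusted over the list alone and 0 were past it over all genes.

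**Figure D2:**
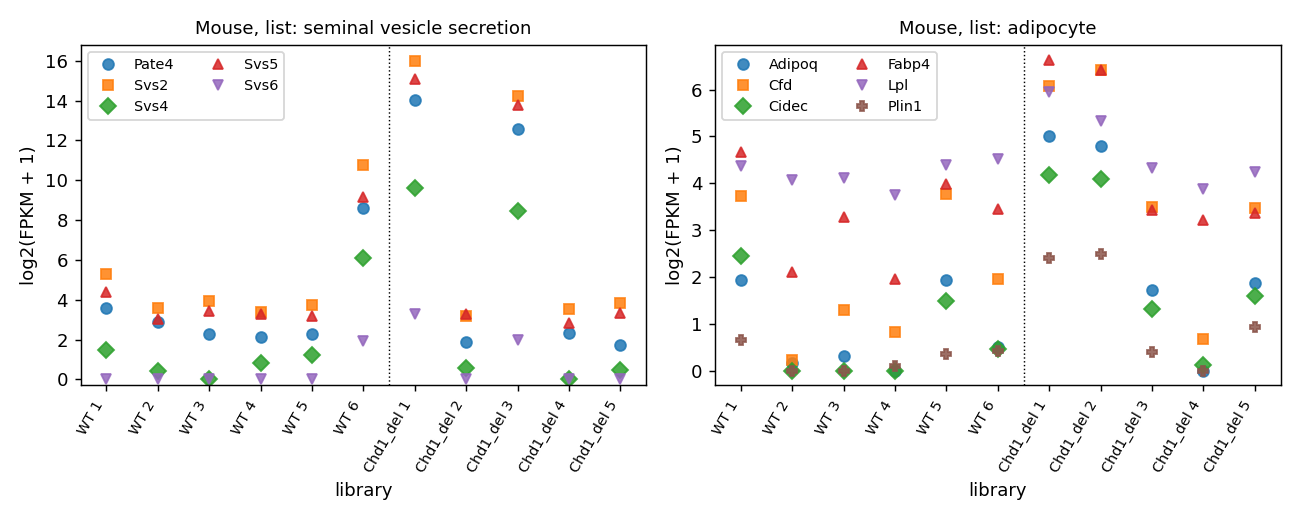
Log2(FPKM + 1) of seminal vesicle and adipocyte genes in each of the 11 mouse libraries, one point per gene and library. Seminal vesicle genes are high in Chd1_del 1 and 3 and in WT 6 (Svs2 at 65980, 19370 and 1743 FPKM), and adipocyte genes in Chd1_del 1 and 2 (Fabp4 at 97.7 and 84.9 FPKM).

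No other cell-type or pathway list passed in mouse with camera. Basal epithelial genes had a median of 0.09 over 10 genes (camera adjusted p = 0.0512), with Krt14 at 14.3 ± 4.08 FPKM (n = 6) in WT and 18.1 ± 2.15 (n = 5) in Chd1_del, and luminal genes −0.05 over 15 (0.317). The unfolded protein response had a median of 0.15 over 18 genes (adjusted p = 0.0971), proliferation −0.16 over 15 (0.124), androgen-responsive genes 0.08 over 22 (0.81), p53 targets 0.03 over 21 (0.81), interferon response 0.04 over 16 (0.812), NF-kB targets −0.02 over 12 (0.81) and ribosome biogenesis −0.04 over 15 (0.706). Smooth muscle had −0.03 over 11 genes (0.992) and endothelium 0.06 over 8 (0.81). Median, mean and test differed in sign for glycolysis and hypoxia (median 0.00, mean 0.10, camera lower, adjusted p = 0.992), mesenchymal transition (0.00, −0.03, higher, 0.992), fibroblasts (0.02, −0.03, lower, 0.81) and immune cells (−0.05, −0.02, higher, 0.812). Ncam1 (0.11) was the neuroendocrine gene tested, and Ckm (0.11) and Acta1 (−0.07) the skeletal muscle genes.

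The authors' deposited table holds 118 genes with a q-value under 0.05, 80 of them higher and 38 lower in Chd1_del. In the authors' deposited table Svs2 was 56.1 times higher, Cdo1 30.7 times and Adipoq 11.4 times in Chd1_del, each with the smallest q-value of 0.00653. Of the lower genes, Jun had a ratio of 0.604 and Fam195b 0.586 in the authors' deposited table. Of 117 of these genes that were tested with limma, 27 had an unadjusted p under 0.05, and Fam195b was the 1 whose groups did not overlap. Among the 80 higher genes, 51 (63.8%) had Chd1_del 1 and 3 as the highest libraries, against 4.54% of tested genes that were higher in Chd1_del in the authors' deposited table without such a q-value. Another 14 (17.5%) had Chd1_del 1 and 2, against 7.44%. Of the 38 lower genes, 14 (36.8%) had WT 5 and 6 as the highest libraries, against 9.9% of tested genes that were lower without such a q-value. WT 5 and 6 are the WT animals without floxed alleles. They also form a series of animal identifiers of their own, so allele and series cannot be told apart.

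Single genes differed between hom_del and wildtype 22Rv1 cells. In the labels the 3 libraries of each edited group share a name prefix, as replicates of a single clone would. Differences of either edited group from wildtype are therefore not separated from differences between clones. HOXB9, a homeobox gene, rose from 1.45 ± 0.644 FPKM (n = 3) in wildtype to 16.7 ± 2.24 (n = 3) in hom_del. GATA3, a transcription factor of luminal lineages, rose from 1.20 ± 0.665 to 10.5 ± 1.86, and EFNB2, an ephrin ligand, from 5.09 ± 0.681 to 29.4 ± 4.88. The amino acid transporter gene SLC7A8 fell from 21.1 ± 4.9 FPKM (n = 3) to 0.454 ± 0.145 (n = 3), the splicing regulator gene MBNL2 from 7.32 ± 0.362 to 0.243 ± 0.208, and STAT6, which carries interleukin signals, from 6.96 ± 2.65 to 0.187 ± 0.102. Of 12531 genes 328 passed the threshold with limma, 106 higher and 222 lower. The largest rises were HOXB9 (log2 fold change 2.88, SE 0.236, adjusted p = 0.000212), PCDH19 (2.44, 0.000654), GATA3 (2.41, 0.00194), BMP6 (2.40, 0.00593), EFNB2 (2.31, 0.000411), CNBD1 (2.12), SNTG1 (2.06), AK5 (2.01), CROT (1.99) and HOXB6 (1.97). The largest falls were SLC7A8 (−3.91, SE 0.227, adjusted p = 2e-05), ALB (−3.08, 0.0201), COL8A1 (−2.76, 0.000372), MBNL2 (−2.76, 0.000212), PRUNE2 (−2.76, 0.000212), GALNT7 (−2.74), STAT6 (−2.69, 0.000959), S100A10 (−2.66), IFT57 (−2.63) and HMGB2 (−2.51, 0.0214). Of these 20 genes 16 passed whichever single library was left out. AK5 missed the threshold without wildtype 1 (adjusted p = 0.0565), wildtype 2 (0.0583) or hom_del 2 (0.0622), HOXB6 without hom_del 2 (0.0515) or hom_del 3 (0.0779), ALB without wildtype 1 (0.0699), wildtype 2 (0.0706), hom_del 2 (0.0662) or hom_del 3 (0.0572), and HMGB2 without wildtype 1 (0.0826), wildtype 2 (0.067), hom_del 2 (0.0875) or hom_del 3 (0.0745). The count was 93 without wildtype 1, 135 without wildtype 2, 81 without hom_del 2 and 107 without hom_del 3.

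The share of higher genes in hom_del depended on scaling. It was 32.3% in the values as deposited, 49.7% of 290 genes with upper-quartile scaling and 46.3% of 272 with quantile scaling. The median log2 fold change over all genes was −0.12 as deposited. That shift was not subtracted, so fold changes and list medians from the values as deposited include it. The composition of the libraries also separated the groups: summed FPKM of small nuclear and nucleolar RNAs was 1248156 to 2232795 in wildtype and 3165820 to 5693714 in the 6 edited libraries. Groups did not overlap for 3048 genes (24.3%, against 10% by chance).

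Neuroendocrine and neuronal genes were lower in hom_del. CHGA, a secretory granule protein gene, fell from 3.40 ± 1.33 FPKM (n = 3) in wildtype to 0.285 ± 0.127 (n = 3), and SNAP25, of the vesicle fusion machinery, fell from 5.66 ± 2.85 to 0.868 ± 0.263. CHGA (log2 fold change −1.74, SE 0.252, adjusted p = 0.00664) passed whichever single library was left out, while SNAP25 (−1.74, SE 0.318, 0.0201) missed the threshold without wildtype 1 (0.0686), wildtype 2 (0.0685), hom_del 2 (0.0606) or hom_del 3 (0.0533). All 7 tested members were lower, with a median of −0.67 (camera adjusted p = 0.000669, adjusted p = 0.218 with an estimated correlation, fry adjusted p = 0.00392, and camera 0.0539 with a minimum mean of 5 FPKM). Of the 7, 2 passed over all genes and 5 adjusted over the list alone. All 18 sterol synthesis genes were also lower, with a median of −0.82 (camera adjusted p = 0.00723, adjusted p = 0.95 with an estimated correlation), although 0 members passed over all genes or adjusted over the list alone. HMGCS1 was at 87.3 ± 5.32 FPKM (n = 3) in wildtype and 37.1 ± 38.7 (n = 3) in hom_del (adjusted p = 0.178), with 81.7 in hom_del 1, 15.6 in hom_del 2 and 13.9 in hom_del 3. The sterol list missed the threshold without hom_del 2 (0.149) or hom_del 3 (0.198).

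DNA repair genes were not called in hom_del. In homologous recombination 0 of 24 genes passed (median −0.38, camera adjusted p = 0.422), in end joining 0 of 15 (−0.16, 0.879), in alternative end joining 0 of 9 (−0.20, 0.892) and in damage signalling 0 of 17 (−0.35, 0.422), where RNF8 (−1.05, adjusted p = 0.0744 over all genes) was the 1 past the threshold adjusted over the list alone. In proliferation 0 of 27 passed (−0.71, 0.326) and in the interferon response 0 of 11 (−0.03, 0.892). Single members of other lists passed. ST8SIA4, a sialyltransferase gene near CHD1, fell from 3.03 ± 0.455 FPKM (n = 3) to 0.797 ± 0.203 (n = 3), PERP, a desmosomal p53 target, from 61.7 ± 7.92 to 26.7 ± 0.935, and vimentin (VIM) from 7.20 ± 2.57 to 1.12 ± 0.527, while the androgen-responsive protease gene TMPRSS2 rose from 7.08 ± 1.42 to 14.4 ± 3.12. CHAC1 (−1.70) and POLR1A (−0.88) also fell. Of these 6 genes VIM passed whichever single library was left out. ST8SIA4, TMPRSS2, CHAC1 and POLR1A missed the threshold without each of wildtype 1 to 3 and hom_del 1 to 3, with an adjusted p of 0.0637 to 0.148, 0.0572 to 0.175, 0.0939 to 0.145 and 0.0652 to 0.124. PERP missed it without wildtype 2 (0.0699), wildtype 3 (0.0544), hom_del 2 (0.0875) or hom_del 3 (0.0689). Their lists had medians of −0.35 for the 7 neighbours (camera adjusted p = 0.422), −0.07 for 22 p53 targets (0.892) and −0.18 for the 9 CHD genes (0.422). Signs differed for 21 androgen-responsive genes (median 0.12, mean −0.02, camera higher, 0.422), the unfolded protein response (−0.11, −0.15, higher, 0.892), glycolysis and hypoxia (−0.06, −0.15, higher, 0.892), ribosome biogenesis (−0.06, −0.05, higher, 0.879), immediate early genes (−0.01, 0.10, higher, 0.422) and luminal genes (−0.15, −0.10, higher, 0.879).

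More genes passed the threshold between het_del and wildtype. REG4, a secreted lectin gene, rose from 4.86 ± 2.74 FPKM (n = 3) in wildtype to 51.5 ± 24.3 (n = 3) in het_del, and the immediate early gene EGR1 from 3.68 ± 2.96 to 24.5 ± 9.9. TFPI, a coagulation inhibitor gene, fell from 21.4 ± 1.78 FPKM (n = 3) to 0.374 ± 0.141 (n = 3). The amino acid transporter genes SLC7A8 and SLC7A5 fell from 21.1 ± 4.9 to 0.590 ± 0.0638 and from 97.5 ± 45.4 to 10.9 ± 3.97, and the gap junction gene GJA1 from 11.9 ± 2.44 to 0.0505 ± 0.0463. With limma 1158 genes passed, 356 higher and 802 lower. The largest rises were REG4 (log2 fold change 3.17, SE 0.361, adjusted p = 0.00143), PPP1R1B (3.05, 0.0154), ZNF876P (2.90, 0.000239), PTN (2.72, 0.00332), HLA-DMB (2.67), EGR1 (2.55, 0.0106), DSEL (2.28), LPXN (2.23), EGFL7 (2.21) and CRYM (2.12). The largest falls were LGALS1 (−4.85, SE 1.07, adjusted p = 0.0215), ALB (−4.17, 0.00339), TFPI (−4.03, 8.67e-06), SLC7A8 (−3.77, 9.76e-06), WBP5 (−3.70, 9.76e-06), GJA1 (−3.60), ZNF512 (−3.34), IGFBP3 (−3.21), GPX8 (−3.03) and SLC7A5 (−3.02). Of these 20 genes 17 passed whichever single library was left out. EGR1 missed the threshold without het_del 3 (0.062), PPP1R1B without wildtype 1 (0.0611), wildtype 2 (0.0556) or het_del 3 (0.0783), and LGALS1 without wildtype 1 (0.0774), wildtype 2 (0.0691), het_del 2 (0.0809) or het_del 3 (0.105). The count was 273 without wildtype 1, 480 without wildtype 2, 1934 without het_del 1, 245 without het_del 2 and 182 without het_del 3.

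Scaling moved the balance of changes in het_del as well. The share of higher genes was 30.7% as deposited, 56.4% of 1180 with upper-quartile scaling and 50.9% of 1056 with quantile scaling. The median over all genes was −0.16 as deposited and 0.02 with upper-quartile scaling, so the excess of falls did not hold with either scaling. Groups did not overlap for 3971 genes (31.7%, against 10% by chance).

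Homologous recombination, damage signalling and proliferation genes ranked lower in het_del than in wildtype with camera at its preset correlation. None of these lists passed with an estimated correlation or with fry. RAD50, of the complex that binds broken ends, fell from 29.1 ± 7.48 FPKM (n = 3) to 15.6 ± 1.27 (n = 3), MRE11A of the same complex from 3.21 ± 0.275 to 1.16 ± 0.478, and BRCA2 from 6.20 ± 1.23 to 2.22 ± 1.72. POLQ, the polymerase of alternative end joining, fell from 5.25 ± 0.657 to 1.81 ± 1.46, and the checkpoint kinase gene CHEK1 from 35.7 ± 3.55 to 12.6 ± 11.4. MKI67, a marker of dividing cells, fell from 16.9 ± 1.23 to 5.22 ± 4.99. In homologous recombination 22 of 24 genes were lower, with a median of −0.90 (camera adjusted p = 0.00122, adjusted p = 0.759 with an estimated correlation), and 4 passed over all genes (MRE11A, BRCA2, RAD50 and FANCI), 10 adjusted over the list alone. In damage signalling 17 of 17 were lower, with a median of −0.90 (0.00122, and adjusted p = 0.759 with an estimated correlation), and 5 passed (TOPBP1, RNF8, CDC25A, CHEK1 and, named after its value was seen, ATM), 7 adjusted over the list alone. In proliferation 27 of 27 were lower, with a median of −1.47 (7.08e-05, and adjusted p = 0.759 with an estimated correlation), and 4 passed (MKI67, BUB1B, AURKB and FOXM1), 11 adjusted over the list alone. With fry the adjusted p was 0.157 for these 3 lists. In end joining RIF1 (−0.93) and PAXIP1 (−0.78) fell among 15 genes, 2 adjusted over the list alone (median −0.25, camera adjusted p = 0.48), and in alternative end joining POLQ (−1.27) among 9, 1 adjusted over the list alone (−0.66, 0.271). Each of the 6 genes with values above missed the threshold without wildtype 1, het_del 2 or het_del 3, at 0.0712 to 0.168. Without wildtype 2 the adjusted p was 0.0566 for MRE11A, 0.115 for BRCA2, 0.103 for POLQ, 0.0871 for CHEK1 and 0.0681 for MKI67. Without wildtype 3 it was 0.12 for RAD50, 0.0586 for BRCA2, 0.0672 for POLQ, 0.0899 for CHEK1 and 0.052 for MKI67, and without het_del 1 0.0523 for RAD50. RIF1 and PAXIP1 missed the threshold without wildtype 1 (0.0897 and 0.0883), wildtype 2 (0.0681 and 0.0849), het_del 2 (0.106 and 0.136) or het_del 3 (0.119 and 0.161), and PAXIP1 without wildtype 3 (0.093). Of the 6 fits without 1 library, FANCI, TOPBP1, CDC25A, BUB1B, AURKB and FOXM1 each passed in 1 and RNF8 in 2. ATM passed without wildtype 1 alone (0.0495) and was at 0.0641 to 0.144 in the other 5. The falls were carried by het_del 2 and 3: against the wildtype mean, the median of proliferation was 0.10 in het_del 1, −2.39 in het_del 2 and −1.88 in het_del 3, and that of homologous recombination was −0.04, −1.46 and −1.09.

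Immediate early and luminal genes ranked higher in het_del with camera at its preset correlation. Neither list passed with an estimated correlation or with fry. NR4A1 rose from 1.64 ± 1.04 FPKM (n = 3) to 7.30 ± 4.13 (n = 3) and JUNB from 13.7 ± 6.27 to 39.4 ± 20.2, whereas MYC fell from 44.1 ± 10.5 to 20.6 ± 8.53. The list was higher in 11 of 15 members, with a median of 1.11 (camera adjusted p = 7.08e-05, adjusted p = 0.759 with an estimated correlation, fry 0.157), and 8 members rose and 1 fell adjusted over the list alone, against 3 and 1 over all genes. The homeobox gene HOXB13 rose from 39.9 ± 10.2 FPKM (n = 3) to 70.7 ± 11.5 (n = 3), and luminal genes were higher in 9 of 11, with a median of 0.28 (0.0375, adjusted p = 0.759 with an estimated correlation, fry 0.157). The luminal list missed the threshold with quantile scaling (0.0705) and without wildtype 1 (0.106) or het_del 1 (0.0594). CHGA rose from 3.40 ± 1.33 to 8.63 ± 0.817, in a neuroendocrine list with a median of 0.00 (0.48). Fibronectin (FN1) rose from 13.7 ± 6.08 to 58.6 ± 36, and VIM fell from 7.20 ± 2.57 to 0.511 ± 0.292. VIM passed whichever single library was left out. Without het_del 3 the adjusted p was 0.185 for NR4A1, 0.197 for JUNB, 0.117 for HOXB13, 0.0905 for CHGA and 0.0877 for FN1, and without het_del 2 it was 0.135 for MYC, 0.153 for HOXB13 and 0.0798 for CHGA. Without het_del 1 it was 0.0921 for NR4A1 and 0.0692 for JUNB. Leaving out wildtype 1 gave 0.0661 to 0.162 and wildtype 2 gave 0.0526 to 0.122 for these 6 genes, and wildtype 3 gave 0.102 for NR4A1, 0.0518 for MYC and 0.0818 for HOXB13.

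Remaining lists had fewer calls in het_del. Of 21 androgen-responsive genes 3 rose, SORD (1.17), SLC45A3 (1.21) and MAF (1.35, named after its value was seen), and 2 fell, ZBTB10 (−1.11) and ELL2 (−1.47), against 7 and 4 adjusted over the list alone (median 0.11, camera adjusted p = 0.145). PERP (−1.17) and TP53INP1 (−0.84) fell among p53 targets (−0.26, 0.48), POLR1A (−0.93) and FBL (−0.79) in ribosome biogenesis (−0.42, 0.145), FDFT1 (−1.49) in sterol synthesis (−0.56, 0.203) and ST8SIA4 (−0.97) among the neighbours of CHD1 (−0.72, 0.302). HK2 (−1.01) fell in glycolysis and hypoxia, whose median of −0.21 and mean of −0.08 were negative while camera ranked it higher (0.809). Without het_del 3 the adjusted p was 0.0569 for SORD, 0.0536 for ELL2, 0.0555 for PERP, 0.157 for TP53INP1, 0.0818 for POLR1A, 0.114 for FBL, 0.171 for FDFT1, 0.176 for ST8SIA4 and 0.158 for HK2. Without het_del 2 it was 0.0952 for SLC45A3, 0.104 for TP53INP1, 0.159 for FBL, 0.149 for FDFT1 and 0.174 for HK2, and without het_del 1 0.0857 for ST8SIA4. MAF missed the threshold without wildtype 1 (0.114), wildtype 2 (0.09), het_del 1 (0.0608) or het_del 3 (0.149). Without wildtype 1 it was 0.0529 to 0.131 for SLC45A3, ZBTB10, TP53INP1, POLR1A, FBL, FDFT1, ST8SIA4 and HK2. For TP53INP1, FBL, FDFT1, ST8SIA4 and HK2 it was 0.0806 to 0.131 without wildtype 2 and 0.0565 to 0.0743 without wildtype 3. The CHD family had a median of −0.21 (0.48), the interferon response 0.14 (0.432) and the unfolded protein response −0.34 (0.67). Fewer than 5 genes were tested in human for NF-kB targets (4), mesenchymal transition (4), smooth muscle (3), basal epithelium (2), fibroblasts (2), adipocytes (2) and skeletal muscle (1), and 0 for endothelium, immune cells, seminal vesicle and urothelium.

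**Figure D3:**
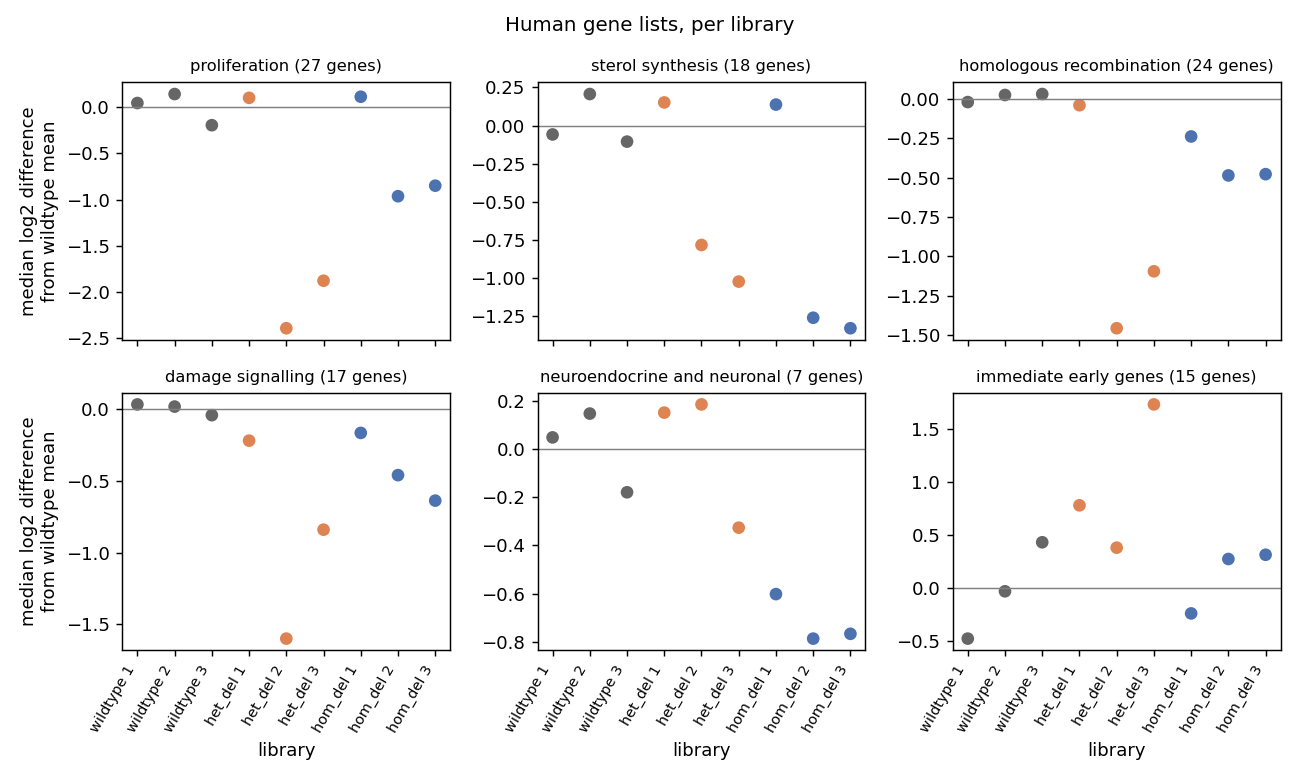
Median log2 difference from the wildtype mean for 6 gene lists in each of the 9 human libraries, one point per library. For proliferation, het_del 1 (0.10) and hom_del 1 (0.11) lie with wildtype, and the other edited libraries lie at −0.85 to −2.39.

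The edited groups were compared with each other to ask whether the second allele mattered. IGFBP3, a growth factor binding protein gene, was at 2.93 ± 1.52 FPKM (n = 3) in het_del and 50.2 ± 11.6 (n = 3) in hom_del. GATA3 was at 0.982 ± 0.44 and 10.5 ± 1.86. HLA-C, which presents antigen, was at 36.9 ± 2.01 in het_del and 2.29 ± 1.47 in hom_del, with the caution that HLA genes share sequence, and CHGA at 8.63 ± 0.817 and 0.285 ± 0.127. With limma 220 genes passed, 51.4% of them higher and 107 lower in hom_del, and groups did not overlap for 2582 genes (20.6%, against 10% by chance). The largest rises were IGFBP3 (log2 fold change 3.75, SE 0.288, adjusted p = 0.000433), GJA1 (3.27), GATA3 (2.54), AK5 (2.51), HOXB9 (2.49), C11orf92 (2.48), ZNF512 (2.43), RND3 (2.43), WBP5 (2.42) and PHLDB2 (2.37). The largest falls were HLA-C (−3.64, SE 0.338, adjusted p = 0.000637), CRYM (−3.25), CHGA (−2.91, 0.000632), PPP1R1B (−2.74, 0.0474), FN1 (−2.73), AKR1C2 (−2.73), HLA-DMB (−2.70), CEACAM6 (−2.57), ID1 (−2.53) and RCAN3 (−2.36). All 10 rises and 7 of 10 falls passed whichever single library was left out. CEACAM6 missed the threshold without het_del 3 (0.101) or hom_del 2 (0.0607), ID1 without het_del 2 (0.0602), het_del 3 (0.128), hom_del 2 (0.109) or hom_del 3 (0.106), and PPP1R1B without het_del 1 (0.0781), het_del 2 (0.0877), het_del 3 (0.204), hom_del 2 (0.157) or hom_del 3 (0.18). The count was 344 without het_del 1, 64 without het_del 2, 86 without het_del 3, 80 without hom_del 2 and 93 without hom_del 3. The labels do not state whether each edited group descends from a single clone, so here too clone and genotype were not separated.

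With camera at its preset correlation 7 lists differed between the edited groups, 4 higher and 3 lower in hom_del. None of them passed with an estimated correlation, and 1 passed with fry. Of neuroendocrine genes CHGB fell from 8.66 ± 3.03 FPKM (n = 3) in het_del to 2.38 ± 0.797 (n = 3) in hom_del and SYP from 18.9 ± 2.5 to 9.39 ± 1.2. That list was lower in 6 of 7 members, with a median of −0.72 (camera adjusted p = 6.69e-05, adjusted p = 0.131 with an estimated correlation, fry 0.00435), and 3 members passed over all genes and 3 adjusted over the list alone. Immediate early genes were lower in 13 of 15 (median −0.77, 0.000239), and luminal genes in 7 of 11 (−0.40, 0.0376), both with an adjusted p = 0.814 with an estimated correlation. Of the immediate early genes IER2 (−1.52) fell over all genes, and 4 fell and 1 rose adjusted over the list alone. Proliferation was higher in 26 of 27 (0.83, 0.00044), homologous recombination in 21 of 24 (0.51, 0.00212), damage signalling in 16 of 17 (0.48, 0.0043) and ribosome biogenesis in 15 of 16 (0.33, 0.0117), with 0 members past the threshold over all genes in these 4 lists and 1, in ribosome biogenesis, adjusted over the list alone. Each of these 4 lists also had an adjusted p = 0.814 with an estimated correlation. Without het_del 2 the threshold was missed by proliferation (0.261), homologous recombination (0.22), damage signalling (0.138), ribosome biogenesis (0.104) and luminal genes (0.059), and without hom_del 3 by luminal genes (0.0988). SLC45A3 (−1.71), STEAP2 (−1.76) and the interferon gene STAT2 (−1.51) fell and ZBTB10 (1.29) rose. Without het_del 2 the adjusted p was 0.0877 for CHGB, 0.17 for SYP, 0.0514 for IER2, 0.0546 for SLC45A3, 0.0877 for STEAP2 and 0.0602 for STAT2. Without hom_del 3 it was 0.0819 for CHGB, 0.113 for SYP, 0.181 for IER2, 0.0664 for STEAP2 and 0.0514 for ZBTB10, and without hom_del 2 0.151 for SYP, 0.169 for IER2, 0.0522 for STAT2 and 0.0589 for ZBTB10. Without het_del 3 it was 0.0886 for SYP, 0.205 for IER2 and 0.0727 for STEAP2, and without het_del 1 0.0712 for IER2. No call was made for end joining (0.11, 0.714), alternative end joining (0.31, 0.175), p53 targets (0.04, 0.714), the interferon response (−0.04, 0.355), the unfolded protein response (0.10, 0.661) or sterol synthesis (−0.17, 0.208). Signs of median, mean and camera differed for androgen-responsive genes (0.12, −0.07, lower, 0.575), glycolysis and hypoxia (0.16, −0.08, higher, 0.888), the neighbours of CHD1 (−0.03, 0.16, higher, 0.931) and the CHD family (0.03, −0.01, lower, 0.814).

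Many genes changed in the same direction in both edited groups. SLC7A8, ALB and VIM fell and CHD1 itself fell in each. Of the 106 genes that rose in hom_del 51.9% also rose in het_del, and of the 222 that fell in hom_del 52.3% also fell in het_del. Since both comparisons share the wildtype libraries, no overlap expected by chance is given. The 4 that went in opposite directions, named after their values were seen, were CHGA, AKR1C2, HLA-C and TRPS1, each higher in het_del and lower in hom_del. Across genes, which are not independent replicates, Pearson's r between the fold changes was 0.656. Both comparisons share the 3 wildtype libraries, which alone gave r of 0.438 (95% of 100 simulations within −0.401 to 0.915). The covariance of 0.200 was above the simulated mean of 0.047 and its upper bound of 0.105. With separate controls, 1 wildtype library for one edited group and the other 2 for the other, the covariance was positive in all 6 assignments, with a mean of 0.144 (0.113 to 0.171, r of 0.278 to 0.452). The excess over the simulated mean was 0.153, so variation between the shared wildtype libraries did not account for all of it. A state common to the 3 wildtype libraries would enter both comparisons even with separate controls, and cannot be told apart here. The same holds for a state shared by replicates 2 and 3 of both edited groups, where proliferation and sterol synthesis genes were lower.

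**Figure D4:**
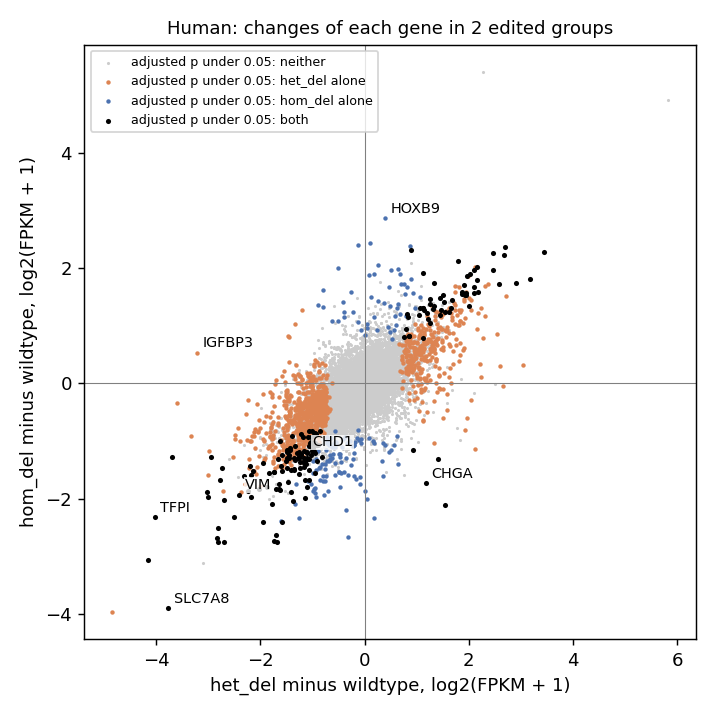
Log2 fold change of each of 12531 genes in hom_del (vertical) and het_del (horizontal) against wildtype, coloured by the comparison in which a gene passed. Of genes past the threshold in hom_del, 51.9% of the higher and 52.3% of the lower ones passed in the same direction in het_del, and 4 in the opposite direction.

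Mouse and human changes were matched for 8154 genes. No gene passed in both species, since 0 passed in mouse with limma, against 191 in hom_del and 685 in het_del. At an unadjusted p under 0.05, 53 genes were shared with hom_del (50.5 expected), 29 of them (54.7%) with the same sign, and Fisher's exact test on direction gave p = 0.58. For het_del 88 were shared (77.1 expected), 56 of them (63.6%) with the same sign, with p = 0.0172 in Fisher's exact test, 1 of a family of 2. Both Fisher's tests take genes as independent, which genes that vary together are not, so these p-values may be too small. Spearman's rho across genes, which are not independent replicates, was 0.079 and 0.131.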

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

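The tests on other tissues, on growth state, on scaling and on an effect in every edited library were chosen after the results were seen, while the comparisons with other splits of the samples were set beforehand.

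Single mouse libraries stood apart from their group in 3 of 72 checks of list medians, sums of FPKM and values of named genes, where chance gives about 1 in 20. All 3 were list medians. The seminal vesicle list was 4.76 above the WT mean in WT 6, against −1.24 to −0.04 in the other WT libraries. The immune cell list was 0.83 in Chd1_del 2, against −0.31 to −0.04 in the other Chd1_del libraries. Homologous recombination was 0.19 in WT 5, against −0.12 to −0.03 in the other WT libraries.

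The edited 22Rv1 groups differed from each other in 7 lists in a direct camera test of hom_del against het_del. None of the 7 passed with an estimated correlation (smallest adjusted p = 0.131), and 1 passed with fry (neuroendocrine genes, adjusted p = 0.00435). The median in hom_del minus that in het_del was 0.51 for homologous recombination, 0.48 for damage signalling, 0.83 for proliferation and 0.33 for ribosome biogenesis. It was −0.77 for immediate early genes, −0.40 for luminal genes and −0.72 for neuroendocrine genes.

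Seminal vesicle transcripts were high in Chd1_del 1 and 3, and adipocyte transcripts in Chd1_del 1 and 2. All 5 tested seminal vesicle genes had Chd1_del 1 and 3 as their highest libraries, with Svs2 at 65980 and 19370 FPKM, and all 6 adipocyte genes had Chd1_del 1 and 2, with Fabp4 at 97.7 and 84.9 FPKM, which restates the pattern and is no test of its source. An effect of the deletion of like size in the 5 animals is argued against by the values that define the pattern. In Chd1_del 4 and 5 Svs2 was at 10.7 and 13.5 FPKM and Fabp4 at 8.34 and 9.35, near the WT medians of 13.3 and 9.37. That 0 of the 11 genes had every Chd1_del library above every WT library follows from the pattern and adds no test. A smaller effect in these animals is not excluded. WT 6 (Svs2 at 1743 FPKM) shows the seminal vesicle genes without Cre. RNA from seminal vesicle in Chd1_del 1 and 3, and RNA from fat in Chd1_del 1 and 2, taken along with the lobe, stay open, as does a response in single animals.

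Proliferation and sterol synthesis genes were lower in replicates 2 and 3 of both edited groups but not in replicate 1. An effect of CHD1 loss of like size in every edited library is argued against by the values that define the pattern: 4 of 4 list medians of het_del 1 and hom_del 1 were inside or above the wildtype range, although CHD1 was at 12.2 and 7.09 FPKM there. A smaller effect in replicate 1 is not excluded. Scaling is argued against too: with upper-quartile scaling the smallest gap between replicate 1 and the others was 0.609, against a range of 0.263 in wildtype. Of the proliferation genes, 24 of 27 (88.9%) had replicate 1 highest in both edited groups, against 29.9% of all genes, which restates the pattern and is no test of its source. Of the homologous recombination genes 13 of 24 (54.2%) and of the damage signalling genes 11 of 17 (64.7%) also had replicate 1 highest in both edited groups. A difference in growth state between cultures therefore stays open, as does an effect of CHD1 loss that depends on it. Both stay open for these repair lists too. Culture density and harvest are not given in the sources used here.

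Other splits of the libraries were run with the same fits. For the mouse genes the real split gave 0, which all 100 splits drawn reach by construction (highest other 4), so this comparison decides nothing. For the mouse lists 81 of 100, the real split included, gave at least the real 3, with 10 as the highest, so chance is not excluded. With 3 against 3 human libraries there are 10 splits, too few for a share under 0.05. The real split was the 1 with as many genes in each human comparison: 328 against a highest other of 0 for hom_del and wildtype, 1158 against 0 for het_del and wildtype, and 220 against 1 for hom_del and het_del. With the real split included, as many lists came from 4 splits for hom_del and wildtype (real 2, highest other 3). They came from 4 for het_del and wildtype (real 5, highest other 6) and from 3 for hom_del and het_del (real 7, highest other 9), again with the real split included. The other splits among these placed hom_del 1 or het_del 1 with 2 wildtype libraries, or het_del 1 and hom_del 1 together with hom_del 2 or hom_del 3. Placed with het_del 2 or het_del 3 instead, het_del 1 and hom_del 1 gave 3 and 2 lists. The counts of lists thus follow replicate 1 only in part. With the replicate number as a block 3, 5 and 7 lists passed, and the labels do not say what the number marks.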

How the results depend on the processing

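The fits without Chd1_del 1 and 3, without Chd1_del 1 to 3, and without het_del 1 and hom_del 1 were chosen after the data were seen. In no setting did a named gene other than the targeted gene, or a called list, reverse. Among fits without 1 library, calls were lost in 45 of 168 for genes named in hom_del, 138 of 318 in het_del and 30 of 162 in hom_del against het_del. Under the other planned settings 19 of 240, 68 of 465 and 10 of 237 were lost.

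In mouse 1 gene passed in place of 0 under quantile scaling, upper-quartile scaling and quality weights (Fam195b) and in the first series of animals (Snora78, −5.15, adjusted p = 0.0288, chosen after its values were seen). Without 1 library the count was 0 to 1, and it was 1 without WT 5. The 3 lists became 0 with an estimated correlation, 0 with fry, 6 with quantile scaling, 5 without Chd1_del 1 and 3, and 6 without Chd1_del 1 to 3. Without 1 library the list count was 2 to 6: 5 without WT 2, WT 4 or WT 6, and 6 without Chd1_del 1 or 2. Chd1 was at 0.003 without Chd1_del 1 to 3, reversed from −0.13, and at −0.18 to −0.07 without 1 library.

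For hom_del against wildtype the 328 genes became 564 with quality weights, 156 with the pair of groups alone and 750 without het_del 1 and hom_del 1, of which 279 were among the 328. Without 1 library the count was 81 to 390. The 2 lists became 0 with an estimated correlation, 1 with fry and 1 at a minimum mean of 5 FPKM, and 1 to 3 without 1 library. CHD1 stayed negative at −1.29 to −1.08 without 1 library, but past the threshold in none of those fits, which hold fewer samples.

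For het_del against wildtype the 1158 genes became 2738 with quality weights and 2257 without het_del 1 and hom_del 1, of which 1071 were among the 1158. Without 1 library the count was 182 to 1934. The 5 lists became 0 with an estimated correlation and 0 with fry, and 4 to 6 without 1 library. CHD1 was at −1.32 to −0.91 without 1 library.

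For hom_del against het_del the 220 genes became 680 with quality weights, and 64 to 344 without 1 library. The 7 lists became 0 with an estimated correlation and 1 with fry, and 2 to 8 without 1 library. CHD1, not called, reversed from −0.08 to 0.105 with quality weights, 0.236 without het_del 1 and hom_del 1, 0.129 without het_del 1 and 0.03 without hom_del 1, within −0.28 to 0.13 without 1 library.

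The covariance above that of simulated groups moved from 0.153 to 0.218 with a pseudocount of 0.1 FPKM. The covariance with separate wildtype libraries, chosen after the data were seen, was 0.144. Genes shared by mouse and human rose from 0 to 53 and 88 at an unadjusted p, by construction. For the other changes the cause was not tested. The planned fits on counts were not run because the values are FPKM. The depth is unknown, so what it limits cannot be stated.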

Other observations

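The classes of RNA and the test of windows between the edited groups were chosen after the values were seen, while the tests on flanking windows and on locus length and level were set before their results were seen.

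Short nuclear RNAs had positive medians in both edited 22Rv1 groups. The 90 H/ACA box small nucleolar RNAs, which guide pseudouridylation, had a median log2 fold change of 1.21 in hom_del (23 past the threshold, all higher) and 1.61 in het_del (66, all higher), and of 0.56 and 0.75 with quantile scaling. The 13 C/D box small nucleolar RNAs had 1.28 (3 higher) and 1.63 (7 higher), and 0.68 and 0.54 with quantile scaling. The 16 Cajal body RNAs had 1.17 (2 higher) and 1.42 (8 higher), and 0.56 and 0.59 with quantile scaling. The 22 spliceosomal and U8 RNAs had 0.76 (3 higher) and 1.19 (9 higher), and 0.28 and 0.76 with quantile scaling. The 7 copies of 7SK had 0.77 (0 past the threshold) and 1.48 (6 higher), and 0.76 and 1.27 with quantile scaling. The 103 genes of up to 150 bases had 1.20 (27 higher) and 1.61 (73 higher), and 0.52 and 0.58 with quantile scaling. No set test was run on these classes. FPKM of such short RNAs depends on fragment size and on the authors' length correction, and reads shared between copies make single members uncertain.

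Histone and mitochondrial genes had negative medians in het_del. The 62 histone genes had a median of −0.91 in hom_del (2 lower) and −1.28 in het_del (14 lower). Against the wildtype mean their median was −0.55, −2.54 and −0.94 in het_del 1, 2 and 3 and −0.28, −1.19 and −1.25 in hom_del 1, 2 and 3, where wildtype libraries had −0.37 to 0.41, so hom_del 1 lay inside the wildtype range. The 14 mitochondrial genes had −1.20 in het_del (10 lower). In hom_del their median was 0.07, with 1 higher, at 0.21 with upper-quartile and −0.14 with quantile scaling. Between the edited groups it was 1.31, with 10 higher in hom_del. The 78 ribosomal protein genes had 0.16 in hom_del (0 past the threshold) and 0.19 in het_del (5 higher). With upper-quartile scaling the medians were 0.30 and 0.41, and with quantile scaling −0.13 and −0.25.

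Stretches of chromosomes were shifted as blocks in the edited groups. In windows of 20 Mb, 85 genes at 140 to 160 Mb of chromosome 8 had a median of 0.49 in hom_del (permutation p = 0.001) and 0.59 in het_del (p = 5e-04, the smallest that 2000 shuffles can give). On chromosome 18, 32 genes at 60 to 80 Mb had 0.40 (permutation p = 0.011) and 0.45 (0.016). In het_del, 42 genes at 0 to 20 Mb of chromosome 8 had −0.57 (permutation p = 0.0015), the adjacent 90 genes at 20 to 40 Mb −0.43 (0.026) and 25 genes at 80 to 100 Mb of chromosome 3 had −0.56 (0.0015). Between the edited groups these 3 windows differed by 0.50 (permutation p = 5e-04), 0.45 (0.002) and 0.52 (5e-04), hom_del minus het_del. On chromosome 4, 35 genes at 20 to 40 Mb had −0.40 in het_del (permutation p = 0.049) and −0.26 in hom_del (0.27), without a difference past the threshold between the edited groups (0.10, p = 1). Of 154 windows 2 passed in hom_del and 6 in het_del. The 20 splits of 3 against 3 libraries allow no p under 0.1, so these permutation p-values do not measure the spread between libraries. Neighbouring genes that vary together may make them too small. No values of single libraries are given for these windows.

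Locus length and expression level are argued against as the source of these blocks, since all 8 window shifts kept at least 65.4% of their median, with 95% bootstrap intervals without 0, once the median of genes of like length and level was subtracted. Copy number that differs between the cell populations is a candidate explanation, and the flanking windows that had not passed themselves did not decide it: 7 of 9 shifted the same way, against 70.9% of neighbouring windows in general (exact one-sided binomial p = 0.488). A window beside a shift that passed in both edited groups was counted once per group, while the binomial test takes windows as independent. GC content was not tested.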
